A study of Mus musculus with 3 samples.

How the data were processed

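Ribosomal RNA-depleted total RNA from the cytosolic fraction of mouse bone-marrow-derived macrophages was sequenced in 3 libraries of 1 group, prepared from 1 µg of RNA with a size range of 250 to 400 bp, per the labels. The cells had received 100 ng/ml lipid A for 120 min. Replicate numbers 1, 2 and 3 were taken from the labels. Each library has 3 tables of values: a gene table and a transcript table in the column layout of RSEM, and a transcript table in the column layout of kallisto. The text listing deposited with each library names mm10 and GENCODE M21 and says that the RSEM-layout tables derive from alignments to the transcriptome and the kallisto-layout table from the reads. The aligner, the versions of all tools and the strand setting are not given in the sources used here. The limit this sets is that overlapping and antisense genes cannot be separated with certainty.

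The authors deposited expected counts, which are model estimates that need not be whole, per gene and per transcript, and estimated counts per transcript in the kallisto layout. Per the file headers, TPM is the authors' length-scaled value, with a fixed sum over all features of a table, including tRNA, spike-in and phiX features. FPKM was deposited beside it and is scaled by length and library total. The percent of a gene's TPM in each transcript is also a deposited column, and was recomputed here from the transcript TPM. The bounds of the credibility interval of TPM, treated as a signal because they have no fixed sum, come from the authors' sampling within a library, per the file headers, and enter no comparison. TPM divides by an effective length, so RNAs near the fragment length gain a large share of the total and all longer RNAs lose it. TPM keeps no depth, and depth was taken from the expected counts: 31152786, 114031592 and 59693298 in replicates 1, 2 and 3.

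All 55536 gene identifiers matched the GENCODE M21 annotation, from which symbols, classes and mm10 coordinates were taken. The tables also hold 26248 tRNA features and 96 ERCC spike-in features. ERCC features had 0 counts in every library and tRNA features at most 5.82. Identifiers that share a symbol, such as those of Rmrp and Aldoa, were added. Kallisto-layout TPM was summed over the transcripts of each gene and is called the second quantification. A gene was called detected at TPM of at least 1 in every library. Levels are means and SDs of TPM over 3 libraries. Values on a log scale are log2(TPM + 1), which understates differences of low genes.

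Lists of genes, the 8 list comparisons and the dispersion test were fixed before the data were examined. The lists were primary and secondary inflammatory, interferon response, immediate early, feedback regulators, TLR4 signalling, macrophage identity, alternative activation, 9 lists of other cell types, proliferation, glycolysis, citric acid cycle, nuclear and cytosolic noncoding RNA, sex-linked and housekeeping genes. Of all members, 2 symbols of the cytosolic noncoding list, Snhg16 and Norad, matched no symbol of the annotation and were left out. In 8 comparisons the difference of list medians was taken in each library, genes in both lists left out, with its mean and SD over the libraries. A two-sided permutation test over genes shuffled list membership 100000 times on the mean over libraries, with Benjamini-Hochberg adjustment over the 8 comparisons at 0.05. The genes named were chosen by a rule: the 10 features with the highest mean TPM, up to 6 highest and 2 lowest members of each list, and the 10 genes with the largest SD of log2(TPM + 1) among those with mean TPM of at least 10 that varied beyond counting error. For the inflammatory, interferon and feedback genes the highest transcript was also named. Other genes are marked in the text as named after their values were seen.

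Expected counts were rounded to whole numbers and the biological coefficient of variation was estimated with edgeR 4.0.16 in R 4.3.3, with TMM factors and an intercept only, for genes with at least 10 counts on average. Variation beyond counting error was tested with a Poisson dispersion test, a chi-square with 2 degrees of freedom, with Benjamini-Hochberg adjustment at 0.05. Other values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Both steps were tested on simulated data. In the dispersion test over 13911 genes, 67.2%, 73.1% and 83.3% of genes changed by 1.25, 1.5 and 2 fold in a library were recovered with 4 false calls, and a simulated coefficient of 0.2 was recovered as 0.201. In 200 runs of the list comparison with 24 genes against 24, 4.5% of unshifted lists and 100% of lists shifted by 3 on the log2 scale passed 0.05. These lists were drawn at random from genes with mean TPM of at least 1. Smaller shifts, lists with lower members and lists of genes that vary together were not simulated.

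Alternatives fixed in advance were other TPM thresholds, another pseudocount, a filter on list members, FPKM, list means, the second quantification, a scale without spike-ins, mitochondrial and ribosomal RNA, DESeq2 1.42.0 size factors, other count minimums, and leaving out each replicate. Rescaling to nuclear-encoded protein-coding genes, the coefficient of variation on those genes alone, the nuclear list without short RNAs and the other cell types without 6 genes also known in myeloid cells were added after seeing the data, as were the tests of explanations that rescale TPM or that cover every detected nuclear noncoding RNA. For each library, a list's median log2 ratio to the mean of the other libraries was placed among 10000 random lists of the same size matched on expression in 20 bins. Confidence intervals for shares of counts are Wilson intervals at 95% and cover counting error only.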

Results

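Total RNA was sequenced after ribosomal RNA depletion from the cytosolic fraction of bone-marrow-derived macrophages of C57BL/6J mice. These are primary phagocytes grown from marrow progenitors. The cells had been exposed for 120 min to 100 ng/ml lipid A, the membrane anchor of bacterial lipopolysaccharide and a ligand of the receptor TLR4. The labels give 1 group of 3 libraries, numbered as biological replicates 1, 2 and 3, with no untreated cells, other time or other fraction. No change caused by lipid A can therefore be measured here. The values below are levels in stimulated cells, differences between gene lists within the same libraries, and the spread between the replicates. The labels give the 3 replicates the same donor identifier and do not say whether they came from separate animals, so an SD or a dispersion test covers only the spread between these samples, which may be technical. The p-values of list comparisons come from shuffled genes and do not measure that spread. The gene tables held 31152786, 114031592 and 59693298 expected counts for replicates 1, 2 and 3. At these depths the limit that a count of 0 allows was 0.0963, 0.0263 and 0.0503 CPM, for counting error only.

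Short noncoding RNAs headed the cytosolic fraction. The RNA component of the signal recognition particle, 7SL RNA, has 2 genes on chromosome 12 of mm10, Rn7s1 at 69159295 to 69159594 and Rn7s2 at 69361182 to 69361481. Together they took 60.4% ± 5.69 of TPM (SD, n = 3). The 10 features with the highest mean TPM held 75.8% ± 2.76 of TPM (SD, n = 3). Besides 7SL they included Rn7sk, the RNA of the 7SK particle that binds the elongation factor P-TEFb, and the RNA component of RNase P (Rpph1). The others were 2 gene entries of the RNase MRP RNA (Rmrp), both ferritin chains (Fth1 and Ftl1), lysozyme (Lyz2) and mt-Atp8. On an effective length of 20.7 nt, mt-Atp8 had 6354, 6945 and 10295 counts in replicates 1 to 3. Lyz2, at a similar mean TPM, had 267796, 998389 and 467644 counts. Nuclear-encoded protein-coding genes took 22.2% ± 1.21 of TPM but 83.8% ± 0.659 of expected counts, and 7SL took 10.04% ± 2.47 of expected counts (SD, n = 3 each). By expected counts the 10 highest features held 19.5%, and in the second deposited quantification 89.8% of TPM. In that quantification 7SL took 19.1% ± 6.05, while the pseudogenes Gm12895 and Gm12896, named after their values were seen, took 42.0% ± 11.9 (SD, n = 3 each). The large share of 7SL in TPM thus held for the gene tables and not for the second quantification. Rn7s1 and Rn7s2 are near-identical copies, so the split of reads between them is uncertain.

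**Figure D1:**
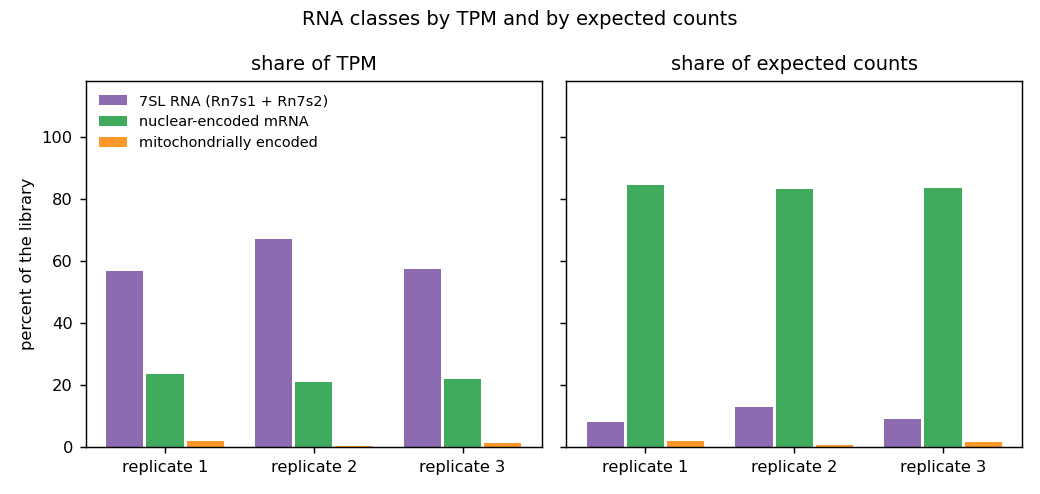
Percent of each library (vertical axis) taken by 7SL RNA, nuclear-encoded mRNA and mitochondrially encoded RNA in replicates 1 to 3, by TPM on the left and by expected counts on the right. Bars are single libraries. 7SL takes between 56.9% and 67.0% of TPM, while nuclear-encoded mRNA takes at least 83.2% of expected counts.

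At TPM of at least 1 in every library, 8699 genes were detected, and single libraries had 9329, 8885 and 9140 such genes. Genes of macrophage identity stood far above markers of other cells. All 34 macrophage genes were detected, with a median level of 251 TPM. They were led by Lyz2 at 4039 ± 316 TPM, the lysosomal proteases Ctsd at 2405 ± 41.3 and Ctsb at 2063 ± 69.3, Gpnmb at 1967 ± 70.2 and Apoe at 1528 ± 247 (SD, n = 3 each). The lowest were Cebpa at 4.38 ± 1.17 TPM and Lyz1 at 1.13 ± 0.0379 TPM (SD, n = 3 each). Lyz1 is a close paralog of Lyz2 and its level is uncertain.

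Of 113 markers of T, B, natural killer, dendritic, mast, erythroid, megakaryocytic, stromal, progenitor and neutrophil cells, 13 were detected and 15 had no counts. The T-cell receptor gene Trac was at 0.0133 ± 0.0153 TPM, and the highest B-cell marker, Cd79b, was at 0.393 ± 0.0208 TPM (SD, n = 3 each). The detected markers included Pf4 at 148 ± 15.0 TPM, Bst2 at 109 ± 18.0, Il7r at 20.8 ± 1.69, S100a9 at 13.5 ± 1.72 and Csf3r at 13.3 ± 1.80 (SD, n = 3 each). The list medians differed by 7.94 ± 0.04 on the log2(TPM + 1) scale, in the same direction in 3 of 3 libraries (SD, n = 3). The other-cell median of 0.0367 TPM lies below the pseudocount of 1, so the size of this difference depends on the setting, from 5.60 to 10.86 over the alternatives. A two-sided permutation test over genes gave p = 1e-05, the smallest that 100000 shuffles can give, with an adjusted p of 4e-05 over the 8 list comparisons. In this and the following list tests the shuffled units are genes, which are not independent replicates, and an exact sign test over 3 libraries cannot go below p = 0.25.

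Inflammatory genes described as direct targets of TLR4 signalling were among the most abundant mRNAs. Of 30 such primary genes, 29 were detected and 15 were at 100 TPM or more in every library, with a median of 129 TPM. Chemokine genes on chromosome 11 led: Ccl4 (83662584 to 83664683) at 1388 ± 384 TPM, Ccl3 (83647844 to 83649355) at 856 ± 218 and Ccl7 at 578 ± 57.1 (SD, n = 3 each). Ccl2, on the same chromosome, was at 519 ± 39.8 TPM (SD, n = 3), below Il1b and Slfn2. Il1b, which encodes the precursor of interleukin 1 beta, was at 554 ± 144 TPM and Slfn2 at 539 ± 20.5 TPM. Tnf, named after its values were seen, was at 373 ± 103 TPM. The tissue factor gene F3 was at 1.62 ± 0.434 TPM, and Csf3, which encodes the granulocyte growth factor G-CSF, at 0.197 ± 0.104 TPM, below detection (SD, n = 3 each).

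Genes described as secondary targets, which need new protein synthesis or nucleosome remodelling, were lower. Of 24, 17 were detected, and the median was 6.28 TPM. Acod1, which makes itaconate from a citric acid cycle intermediate, was at 275 ± 47.0 TPM. The interleukin 12 subunit gene Il12b was at 90.7 ± 16.0 TPM, the collagenase gene Mmp13 at 85.5 ± 23.3, Ccl12 at 76.8 ± 16.3, Ebi3 at 41.4 ± 2.85 and Il27 at 35.5 ± 7.92 (SD, n = 3 each). Il12a, which encodes the partner of Il12b in interleukin 12, was at 0.190 ± 0.0917 TPM and Lif at 0.573 ± 0.275 TPM. Il6 at 11.1 ± 1.77 TPM and Nos2 at 5.41 ± 1.59 TPM were named after their values were seen (SD, n = 3 each). The primary list exceeded the secondary list by 4.24 ± 0.28 on the log2(TPM + 1) scale, an 18.96-fold difference, in 3 of 3 libraries (SD, n = 3; permutation p = 0.00015, adjusted p = 0.0004). With list means the difference was 3.24.

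The interferon list was detected almost completely, with 42 of 43 genes and a median of 51.0 TPM. Its highest members were Cxcl10 at 987 ± 155 TPM, the antiviral gene Rsad2 at 863 ± 148, Ccl5 at 593 ± 24.3, Ifit2 at 357 ± 45.1, Ifit1 at 280.0 ± 63.0 and Ifi205 at 253 ± 7.95 (SD, n = 3 each). Ifnb1, which encodes interferon beta and was named after its values were seen, was at 25.1 ± 7.81 TPM. The lowest members were Isg20 at 7.03 ± 0.586 TPM and Ifna4, with 3 counts in each library. The primary inflammatory list lay 1.36 ± 0.20 above it on the log2(TPM + 1) scale, a 2.57-fold difference, in 3 of 3 libraries (SD, n = 3; permutation p = 0.033, adjusted p = 0.037). This call ended without replicate 1, at 1.30 with an adjusted permutation p of 0.0605, in the second quantification, at 1.39 with 0.0576, and with list means, at 0.51 with 0.399. Over all alternatives the adjusted p ran from 0.0173 to 0.399.

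**Figure D2:**
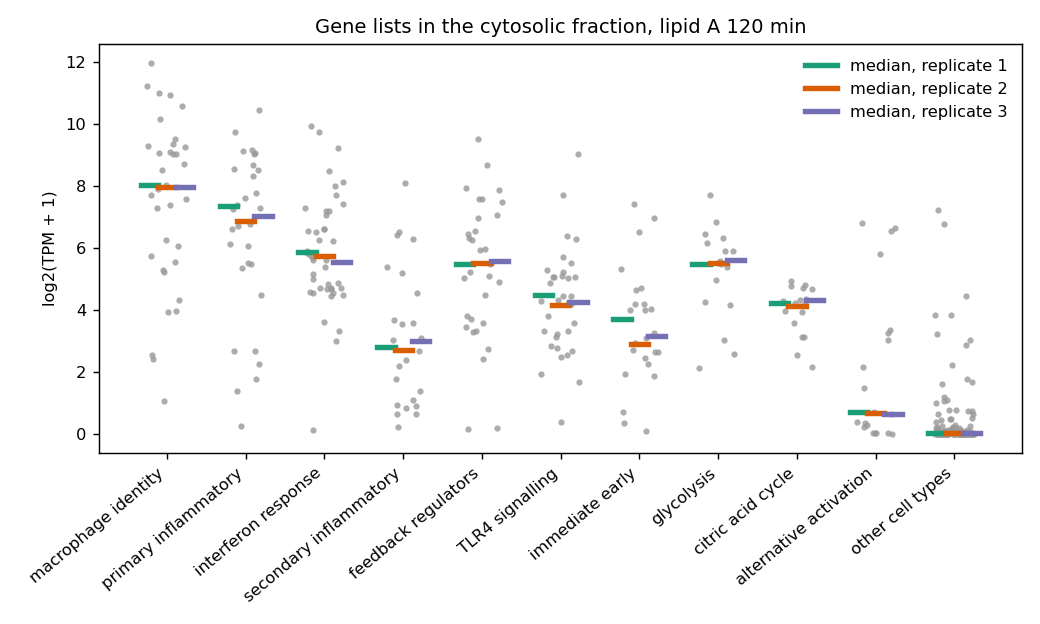
Levels of the members of 10 gene lists and of the pooled markers of other cell types, as log2(TPM + 1) on the vertical axis. Gray points are genes, as means over 3 libraries, and colored bars are the list medians in each replicate. The macrophage and primary inflammatory medians lie highest in each replicate, and the other cell types lie near 0.

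Genes listed as feedback regulators had a higher median than the TLR4 signalling list, which holds receptor, adaptor, kinase and transcription factor genes. Of 31 feedback regulators 29 were detected, with a median of 43.8 TPM. The highest were Tnfaip2 at 739 ± 116 TPM, Nfkbia, which encodes the NF-kB inhibitor IkB alpha, at 405 ± 34.0, Tnfaip3, which encodes the ubiquitin editor A20, at 245 ± 42.6 and Socs3 at 233 ± 13.2. Tnip3 followed at 191 ± 40.5 TPM and Il1rn, which encodes the interleukin 1 receptor antagonist, at 189 ± 3.74 TPM (SD, n = 3 each). Pdlim7 at 0.160 ± 0.0819 TPM and Rgs16 at 0.120 ± 0.0346 TPM were not detected. Of 34 pathway genes 33 were detected, with a median of 18.8 TPM. The coreceptor gene Cd14 was at 524 ± 76.8 TPM, Irf1 at 207 ± 4.94, Nfkb1 at 82.2 ± 8.80, Nfkb2 at 77.6 ± 8.99, Irf5 at 51.7 ± 1.94 and Rela at 44.8 ± 1.16. Mapk8 was at 2.25 ± 0.583 TPM and Tab1 at 0.327 ± 0.0961 TPM (SD, n = 3 each). The lists differed by 1.23 ± 0.20 on the log2(TPM + 1) scale, a 2.34-fold difference, in 3 of 3 libraries (SD, n = 3; permutation p = 0.027, adjusted p = 0.036). With list means in place of medians the difference was 1.05 and the adjusted permutation p 0.052, which ended the call, and over all alternatives it ran from 0.00459 to 0.052.

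Immediate early transcription factors had a median of 8.09 TPM at 120 min. Of 24, 21 were detected and 11 reached 10 TPM in every library. Atf3 was at 171 ± 48.6 TPM, Klf6 at 124 ± 37.4, Junb at 90.2 ± 15.6, Jund at 39.2 ± 4.78, Egr1 at 25.1 ± 12.9 and Maff at 24.1 ± 4.52. Nr4a2 was at 0.287 ± 0.0379 TPM and Fosl1 at 0.0800 ± 0.0458 TPM (SD, n = 3 each). The primary inflammatory list exceeded this list by 3.81 ± 0.17 on the log2(TPM + 1) scale, a 14.1-fold difference, in 3 of 3 libraries (SD, n = 3; permutation p = 0.00035, adjusted p = 0.0007). With list means the difference was 2.94.

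Genes used as markers of interleukin 4 activation were split. Of 20, 9 were detected. The mannose receptor gene Mrc1 was at 111 ± 13.4 TPM, Clec7a at 99.1 ± 21.5, Tgm2 at 92.4 ± 4.13, Il4ra at 55.0 ± 3.24, Clec10a at 9.38 ± 2.36 and Egr2 at 8.59 ± 4.56 (SD, n = 3 each). Retnla had 0, 0 and 2 counts in replicates 1 to 3, and Pdcd1lg2 was at 0.02 ± 0.01 TPM. Arg1, which encodes arginase and was named after its values were seen, was at 0.0400 ± 0.0458 TPM (SD, n = 3 each). The primary inflammatory list lay 6.40 ± 0.24 above on the log2(TPM + 1) scale in 3 of 3 libraries (SD, n = 3; permutation p = 1e-05, the smallest the shuffles can give, adjusted p = 4e-05). The alternative activation median of 0.613 TPM lies below the pseudocount of 1, and the difference ranged from 3.84 to 7.62 over the alternatives.

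All 17 glycolysis genes and all 17 citric acid cycle genes were detected, and glycolysis genes were higher. Gapdh was at 207 ± 11.96 TPM, Aldoa at 114 ± 4.29, Pkm at 86.8 ± 4.76, Ldha at 79.7 ± 2.32, Pgam1 at 70.3 ± 1.99 and Hk3 at 59.3 ± 3.88, with Slc16a3 at 5.04 ± 0.286 and Pfkl at 3.39 ± 0.181 as the lowest. In the citric acid cycle, Sdha was at 29.4 ± 1.10 TPM, Sdhd at 26.96 ± 2.85, Mdh2 at 26.3 ± 2.34 and Sdhb at 25.3 ± 1.10, with Cs at 24.9 ± 1.48, Dlst at 19.5 ± 1.53, Fh1 at 4.83 ± 0.435 and Idh3a at 3.51 ± 0.298 (SD, n = 3 each). The lists differed by 1.31 ± 0.09 on the log2(TPM + 1) scale, a 2.48-fold difference, in 3 of 3 libraries (SD, n = 3; permutation p = 0.0033, adjusted p = 0.0052).

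Noncoding RNAs listed as nuclear were present in the cytosolic fraction. The highest members of this list were Rn7sk at 71235 ± 17534 TPM and Rmrp at 20271 ± 6107 TPM (SD, n = 3 each), above every member of the cytoplasmic list. Malat1, on chromosome 19 at 5795690 to 5802672, was at 577 ± 347 TPM, Neat1 at 35.9 ± 19.1 TPM and Xist at 5.72 ± 4.51 TPM, and Rnu12 was at 33.3 ± 13.4 TPM (SD, n = 3 each) on 6, 20 and 16 counts. Rnu11 and Rny1 are listed at 0 in the gene tables, where their effective lengths of 1.29 and 0 nt leave almost no room for counts, and the second quantification gave Rny1 3.26 ± 0.823 TPM (SD, n = 3). Where the members of either noncoding list lie in these cells was not tested. In the list set in advance as cytoplasmic, Gas5 was at 19.8 ± 5.49 TPM, Mir155hg at 17.0 ± 10.5 and Zfas1 at 10.4 ± 4.50. Snhg8 was at 8.74 ± 2.66 TPM, Dleu2 at 7.87 ± 2.14 and Snhg15 at 6.84 ± 0.193. Dancr was at 0.147 ± 0.0603 TPM and H19 at 0.02 ± 0.0265 TPM (SD, n = 3 each). The cytoplasmic list median was 1.75 ± 0.26 higher on the log2(TPM + 1) scale in 3 of 3 libraries (SD, n = 3), but the difference did not pass the test (permutation p = 0.14, adjusted p = 0.14). Only 7 of the 18 nuclear RNAs were detected. Over members with a mean TPM of at least 1 the difference turned to -2.16, with an adjusted permutation p of 0.0081, and with list means to -1.08, with 0.417. Without the short RNAs of the nuclear list, a choice made after seeing the data, it was 2.07 with an adjusted permutation p of 0.0438. Over all alternatives the difference ran from -2.16 to 3.07 and the adjusted p from 0.0081 to 0.499.

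The replicates were close for most mRNAs. Of the 8699 detected genes, 87.1% had a ratio of highest to lowest library below 1.5, and 96.8% below 2. Across 9148 genes with a mean TPM of at least 1, Pearson's r of log2(TPM + 1) was 0.976 for replicates 1 and 2, 0.983 for 1 and 3, and 0.985 for 2 and 3. These correlations are across genes, which are not independent replicates. The biological coefficient of variation, the spread beyond counting error, was 0.216 over 14037 genes with at least 10 counts on average. Of these genes 8717 varied beyond counting error at an adjusted p of 0.05 in a Poisson dispersion test. These values were 0.244 and 6507 genes without replicate 1, 0.140 and 5205 without replicate 2, and 0.265 and 6901 without replicate 3. Replicate 2 has the most counts, so leaving it out also lowers the power of the dispersion test. For nuclear-encoded protein-coding genes alone the coefficient was 0.129. The test compares libraries of 1 group and no conditions.

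Mitochondrial and nuclear RNAs differed most between the replicates, and replicate 2 was the lowest in both. The cytoplasmic noncoding list was also lower in replicate 2, by less. On deposited TPM, 10 of its 11 detected members were below the mean of the other libraries, with a median log2 ratio of -0.59. Mitochondrially encoded RNA took 1.80%, 0.376% and 1.41% of TPM in replicates 1, 2 and 3, a mean of 1.20% ± 0.735 (SD, n = 3). In the second quantification the mean was 0.458%. All 13 mitochondrially encoded mRNAs were lower in replicate 2 than in the mean of the other libraries. Malat1 was at 741, 178 and 812 TPM, Neat1 at 42.6, 14.4 and 50.8 TPM, and Xist at 5.78, 1.18 and 10.2 TPM in replicates 1 to 3. Small nuclear RNAs took 1.66%, 0.543% and 1.45% of TPM. By expected counts they took 0.0263%, 0.0129% and 0.0231%, a smaller drop in replicate 2 than by TPM. Unprocessed pseudogenes, counted apart from mitochondrially encoded RNA, took 0.922%, 0.220% and 0.829% of TPM. Their share was also lowest in replicate 2, and whether their reads come from mitochondrially encoded RNA was not tested. The 10 genes with the largest SD of log2(TPM + 1), chosen by rule, included mt-Rnr1, a mitochondrial ribosomal RNA, at 35.3, 3.07 and 11.5 TPM. Features annotated as ribosomal RNA took 0.0325%, 0.00451% and 0.0154% of expected counts in replicates 1 to 3. Whether ribosomal RNA depletion differed between the libraries was not tested. Snord17, also among the 10 genes, was at 31.3, 6.19 and 46.5 TPM. Gm26917, annotated as a long intergenic noncoding RNA, was at 272, 46.7 and 541 TPM. The unprocessed pseudogene Gm10222 was at 1169, 179 and 992 TPM. The processed pseudogene Gm14303 was at 169, 2.38 and 2.56 TPM. It had 69.95, 5.42 and 2.06 counts and an effective length of 8.13 nt. The processed pseudogene Gm15899 was at 36.0, 18.1 and 1.84 TPM. The second quantification listed Gm10222, Gm14303 and Gm15899 at 0 TPM, so their levels and spread hold for the gene tables only. The small nuclear RNA copies Gm24830, Gm26232 and Rnu1b6 share the same values, 59.8, 4.8 and 17.3 TPM. Their reads therefore cannot be assigned to a copy. Each copy rests on 20.62, 9.14 and 11.54 counts and an effective length of 6.76 nt. The credibility intervals of Gm24830 were 0.00032 to 208, 5.64e-05 to 19.2 and 0.00147 to 67.8 TPM, so this spread is uncertain. Gm37376, at 0.760, 21.3 and 18.3 TPM, lies within Malat1 at 5801941 to 5802393 on chromosome 19, on the + strand. Its values did not follow those of Malat1 over the replicates. The strand setting is not given, so its reads cannot be separated from those of Malat1 with certainty.

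Inflammatory mRNAs also varied between the replicates, by less. On TPM rescaled to nuclear-encoded protein-coding genes, a scale chosen after seeing the data, 27 of 29 detected primary inflammatory genes were lower in replicate 2 than in the mean of the other libraries, with a median log2 ratio of -0.29. For immediate early genes the median was -0.32 in replicate 2, -0.16 in replicate 3 and 0.39 in replicate 1. The interferon list was at -0.17 in replicate 3, where 35 of 42 genes were lower. In replicate 2 it was at 0.09, at 0.02 in the second quantification and at -0.02 on deposited TPM. Secondary inflammatory genes lay at -0.29 in replicate 2, feedback regulators at -0.14 with 23 of 29 lower, and alternative activation genes at -0.21 with 8 of 9 lower. The pooled markers of other cell types lay at -0.15 with 10 of 13 lower, and the 5 detected neutrophil markers at -0.25, against 0.30 in replicate 3. Macrophage identity genes lay at -0.02 in replicate 2 and all 8275 detected nuclear-encoded protein-coding gene symbols at -0.04. Single chemokine genes moved further: Cxcl2 was at 179, 33.2 and 96.7 TPM and Cxcl1 at 66.9, 20.1 and 45.25 TPM in replicates 1 to 3, both named after their values were seen.

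**Figure D3:**
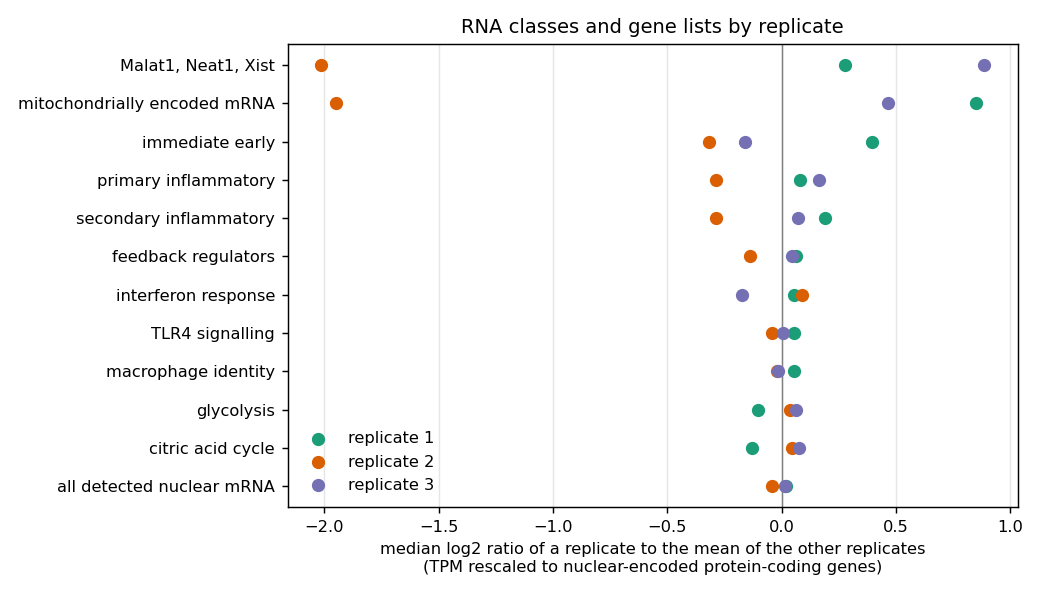
Median log2 ratio of each replicate to the mean of the other replicates (horizontal axis) for RNA classes and gene lists, with TPM rescaled to nuclear-encoded protein-coding genes. Points are single libraries. Malat1, Neat1 and Xist at -2.02 and mitochondrially encoded mRNA at -1.95 in replicate 2 lie farthest from 0.

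For most inflammatory, interferon and feedback genes named above, a main transcript made up nearly all of the gene's TPM. Over 17 genes with at least 2 annotated transcripts and TPM of at least 1, the highest transcript had a median share of 97.0%, and 11 genes were above 90%. Il1b-201, a 7-exon protein-coding transcript on chromosome 2 at 129364570 to 129371139, had 99.5% ± 0.227 of Il1b, and Ccl2-201 had 99.2% ± 0.289 of Ccl2. Isg20-201 had 52.2% ± 11.0 of Isg20, F3-201 had 74.4% ± 5.81 of F3 and Tnfaip2-201 had 76.7% ± 6.45 of Tnfaip2. For Tnip3 the highest transcript was Tnip3-205, annotated as a retained intron with no protein product, at 59.4% ± 7.53 (SD, n = 3 each). The second quantification gave the same highest transcript for 17 of 17 genes. Across 55536 genes Pearson's r between both quantifications was 0.955 ± 0.0093 and Spearman's rho 0.826 ± 0.0104 on the log2(TPM + 1) scale (SD, n = 3 each), again across genes and not independent replicates.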

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

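Reads assigned to phiX, the bacteriophage genome used as a sequencing control, were counted outside the mouse genes and exceeded in every library the 3 counts that a count of 0 allows. PhiX took 204158 expected counts in replicate 1, or 0.655% of its total, with a 95% Wilson interval of 0.653% to 0.658%. The share was 0.0937% (0.0932% to 0.0943%) in replicate 2 and 0.0961% (0.0953% to 0.0969%) in replicate 3. These intervals cover counting error only. Leaving out spike-ins, among other features, moved the number of detected genes from 8699 to 8695.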

How the results depend on the processing

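Of the 8 list comparisons, those of the primary inflammatory list with the secondary, immediate early and alternative activation lists, of glycolysis with the citric acid cycle and of macrophage identity with other cell types kept their direction and side of the threshold under every alternative run. Their differences ranged from 3.24 to 4.43, 2.94 to 3.95, 3.84 to 7.62, 1.21 to 1.35 and 5.60 to 10.86 on the log2 scale. Primary inflammatory minus interferon no longer passed in the second quantification (1.39), with list means (0.51) and without replicate 1 (1.30 to 1.48 over the libraries left out). Feedback minus TLR4 signalling no longer passed with list means (1.05). Cytosolic minus nuclear noncoding RNA reversed over members with mean TPM of at least 1 (-2.16), by construction since that removes undetected nuclear RNAs, and with list means (-1.08). It passed without short nuclear RNAs (2.07). At TPM of at least 5, 4791 genes were detected, against 8699 at 1. The 10 highest features held 89.8% of TPM in the second quantification and 19.5% of expected counts, against 75.8%. The mitochondrial share was 0.458% in the second quantification. The coefficient of variation was 0.129 on nuclear-encoded protein-coding genes and 0.140 to 0.265 over the replicates left out. The genes varying beyond counting error were 5205 to 6901, the lowest without replicate 2, whose removal also takes out the deepest library. The agreement of both quantifications was 0.968 over genes with mean TPM of at least 1, and the median share of the highest transcript was 92.6% in the second quantification. The causes of these shifts were not tested except where named. Of 203 named gene levels, 169 moved by at least 1 SD in the second quantification and 22 with the scale without spike-ins, mitochondrial and ribosomal RNA. Over 126 named genes with TPM of at least 1 the second quantification was at a median of 0.378 times the first, and 1 was higher. TPM has a fixed sum, and in that quantification 2 pseudogenes took 42.0% and 3 features annotated as miRNA took 24.7%. The gene tables list these at 0. Such shares lower all other values, so the count of moved levels does not measure disagreement gene by gene. No paired analysis was possible because the labels give 1 group. Replicate 1, with 31152786 expected counts, limits what can be said of genes near 0.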

Other observations

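Several gene groups outside the comparisons were measured in the same libraries. Of 24 cell cycle genes 9 were detected, led by Pcna at 62.0 ± 2.63 TPM and Mki67 at 22.3 ± 2.22 TPM, while Cenpf was at 0.217 ± 0.0503 TPM (SD, n = 3 each). Among 16 neutrophil markers 5 were detected, with Mmp8 at 3.76 ± 0.564 TPM and Ngp at 2.21 ± 0.495 TPM, and Ly6g had no counts. Of the remaining lists of other cells, 1 of 12 T-cell, 0 of 12 B-cell, 0 of 10 natural killer, 2 of 12 dendritic, 0 of 11 mast, basophil and eosinophil, 1 of 14 erythroid and megakaryocyte, 2 of 16 stromal and endothelial and 2 of 10 progenitor markers were detected. Ly6a, a progenitor marker also known as an interferon-induced gene, was at 11.0, 4.78 and 3.11 TPM in replicates 1 to 3. All 15 housekeeping genes were detected, from Actb at 1814 ± 203 TPM to Tbp at 2.01 ± 0.150 TPM (SD, n = 3 each). The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 counts in the 3 gene tables, while Xist had 5388, 3729 and 16350 counts in replicates 1 to 3. The second quantification listed Uty at 0.0956 TPM on average.

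The second quantification placed most of its TPM in features that the gene tables list at 0. The processed pseudogenes Gm12895 and Gm12896, both of 226 nt on chromosome 4, took 42.0% ± 11.9 of its TPM, and Gm23935, Gm24270 and Gm24245, each of 57 nt and annotated as miRNA, took 24.7% ± 4.52 (SD, n = 3 each). These genes were named after their values were seen. Each set has nearly equal values within a library, so reads cannot be assigned to a copy.

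The tests below of the TPM scale and those over the whole nuclear list were chosen only after the results were seen. The tests of the second quantification on Malat1, Neat1 and Xist and of retained introns were set before. The labels give 1 group, so no biological explanation was tested for any of these patterns.

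The first pattern is the low nuclear and mitochondrial RNA of replicate 2. A high 7SL share lowers all other TPM values of a library by 1 common factor, which rescaling to nuclear-encoded protein-coding genes takes out. For Malat1, Neat1 and Xist rescaling moved the median log2 ratio to the other libraries from -2.12 to -2.02. For mitochondrially encoded mRNAs it moved from -2.06 to -1.95. The shares of the libraries fix the size of this shift, so rescaling could not have removed drops this large. It shows only that the TPM scale accounts for a small part of them. For Malat1, Neat1 and Xist a ratio of -2.00 in the second quantification argues against the choice of quantifier. Over the 7 detected members of the nuclear list, rescaling kept 0.902 of the median (-1.02 before, -0.92 after, 7 of 7 lower). The shares fix this shift in the same way, so here too the TPM scale accounts for only a small part of the drop. On the rescaled scale the second quantification kept 0.577 of the -0.92 (-0.53, 7 of 7 lower). This leaves open how much of the size of the drop depends on the quantifier. Less carry-over of nuclei in replicate 2 stays open. The share of mRNA TPM in retained-intron transcripts was 3.09%, against 3.59% and 3.61% in replicates 1 and 3. The ratio to the lower of these, 0.860, or 0.824 in the second quantification, lies between the limits of 0.8 and 0.95 set for that test. The drop was also not confined to RNAs listed as nuclear. The cytoplasmic noncoding list lay at -0.47 in replicate 2 after rescaling, with 7 of 11 lower. In the second quantification it lay at -0.40, with 8 of 11 lower.

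The second pattern is the lower primary inflammatory and immediate early mRNA in replicate 2. Rescaling, by 1 factor per library, moved the median log2 ratio over 50 genes from -0.40 to -0.29, with 45 of 50 genes lower. That of all detected nuclear-encoded protein-coding genes moved from -0.15 to -0.04. The TPM scale thus accounts for a part of this pattern at most. Of 10000 random lists matched on expression 0% had a lower median, but this also held for the secondary list in replicate 2 and the interferon list in replicate 3. For the immediate early list 100% had a lower median in replicate 1 and 0.01% in replicate 3, and for the primary list 100% in replicate 3. The pattern was picked after its values were seen, and random lists do not hold genes that vary together. This placement is therefore no independent support. Part of the pattern may come from unspliced nuclear transcripts. The median difference in log2 ratio between retained-intron and other transcripts was -0.80 over 17 of the 50 genes. However, 6 of the 17 went the other way, among them Cd83 and Sod2, whose retained-intron levels were the highest. The other transcripts still had a median of -0.18, beyond the limit of -0.1 set for that test, so carry-over of nuclear RNA and a difference in the response cannot be told apart.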
